A study of Caenorhabditis elegans with 4 samples.

How the data were processed

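Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2, grown at 20 °C and fixed in 2% formaldehyde for 30 minutes, per the labels' protocols and the series' design text. The series holds 4 samples: 2 immunoprecipitates made with a rabbit polyclonal antibody against SMC-4, and 2 input samples of DNA taken before immunoprecipitation. Samples were grouped by their titles, which also give the replicate number. Nothing in the labels says whether the replicates came from separate cultures, so differences between them may be technical. The labels' protocols describe the same fixation, sonication and immunoprecipitation for all samples, and give no batch or date.

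Reads were aligned with BWA to ce10, per the submitters' processing notes. The aligner's version is not given in the sources used here. The deposited data used here are 3 peak lists, one for each immunoprecipitate and one for the whole series. All name the genome build WormBase WS220, per the file headers. The last whole-series peaks on I, III and IV end at 15072430, 13783731 and 17493824, which appears to be a few bases past the chromosome ends of that build, whose sequence was not used here. Whether this comes from extension of fragments by the caller or from another build is open, and every position given carries this limit. The replicate lists name MACS and the whole-series list names MACS v2 as the peak caller, per the files' source columns. The control used for calling, the cutoffs, and the way the replicates entered the whole-series list are not given in the sources used here. The replicate lists were called per sample. The whole-series list cannot be treated as independent of them. Peak starts and ends are deposited as 1-based positions, and each peak carries 1 deposited score, which is the authors' peak caller's own value. The scale of the score is not stated, and the ranges of the replicate lists (50.01 to 3100, where values stop) and of the whole-series list (1.31 to 134.49) differ. Score levels were therefore compared within a list. Across lists, score values entered the correlation over overlapping replicate peaks and the comparison of the lowest scores of the 2 replicate lists, which name the same caller and stop at the same value. Between all 3 lists, ranks and percentiles of score, rank correlations of score with width, and ratios of X to autosomal score were compared. Input samples were not analysed here. The lists hold no read counts, so the sequencing depth behind each peak is unknown, and intervals cover counting error of peaks only. Depth, control and cutoff all set how many peaks a list holds.

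From the lists, peak numbers, widths and positions were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Comparisons used the 6 nuclear chromosomes. Peaks on mitochondrial DNA were set aside. No chromosome lengths of build WS220 were used: the span of each chromosome was taken up to the last peak end of any list, which gave 100.3 Mb in all. The gene table at hand belongs to another assembly (WBcel235), so no gene was assigned to a peak, and the planned comparisons with genomic features and gene lists were not run. Regions are named by WS220 position only.

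Peaks of 2 lists were called shared when they overlapped by at least 1 bp. Chance overlap came from 10000 circular shifts of one list within each chromosome (one-sided p). The number of peaks on a chromosome, or in its central 33.3%, was tested against the corresponding share of span by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes or over the 3 chromosome sets. Shares carry 95% Clopper-Pearson intervals, and densities carry exact Poisson intervals. These tests take peaks as independent, which neighbouring peaks are not. Scores and widths were compared by two-sided permutation tests with 100000 resamples, on the difference of medians and on the AUC, the probability that a peak of the first set outranks one of the second. The smallest p these can give is 1e-05, and 0.0001 for the shifts. Spacing was compared with 10000 uniform placements of the same widths. Other 2-way comparisons of counts used two-sided Fisher's exact tests, which were added after the data were seen.

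The regions to be named were fixed before the data were examined: the 20 highest-scoring peaks of the whole-series list, and the highest-scoring peak of each chromosome that peaks of both replicates overlap. Tests, gene lists and most alternatives were fixed then too. The other settings covered the overlap rule (reciprocal 50%, or midpoints within 500 bp), the stronger 50% of each list, merging of peaks within 1 kb, the replicate lists in place of the whole-series list, peaks found in both replicates, uniform placement, equal list lengths, base pairs in place of peaks, the outer 50 kb of chromosomes, the central 50% and other neighbour distances. Scripts were tested on simulated data first. In 200 simulated lists of 1989 peaks with a 1.5-fold X density the mean estimate was 1.49 and 100% were called, and for lists of 296 peaks it was 1.52 with 86.5% called. With no X effect, 4.5% and 5.5% were called. Simulated peaks were placed independently of each other, unlike the grouped peaks of the real lists, so these rates may not carry over. In a simulated list of 296 peaks with 60% copied from the other, 59.8% overlapped.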

Results

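SMC-4 is a structural maintenance of chromosomes ATPase and a core subunit of condensin, the ring-shaped complex that compacts and organises chromosomes. Its binding was mapped by ChIP-seq in mixed-stage wild-type embryos, in 2 immunoprecipitates with 2 input samples. The replicate 1 list held 1176 peaks, of which 1174 lay on the 6 nuclear chromosomes. The replicate 2 list held 296 peaks, all nuclear. Another list, for the whole series, held 1997 peaks, 1989 of them nuclear. Read depth was not given by the lists, so the precision below reflects the number of peaks only.

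Most peaks were short in every list. The median width was 376 bp in replicate 1, 399.5 bp in replicate 2 and 225 bp in the whole-series list. Nuclear peaks covered 689 kb, 255 kb and 633 kb in the 3 lists, or 0.688%, 0.254% and 0.631% of the chromosome span. Replicate 1 thus listed 3.97 times as many peaks as replicate 2 and covered 2.71 times as many bases. The longest peak of each replicate lay at the right end of chromosome I. It ran from 15060186 to 15071361 in replicate 1 (11176 bp) and from 15060198 to 15071349 in replicate 2 (11152 bp), and had the top score of 3100 in both.

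The first question was whether the 2 immunoprecipitates marked the same places. Of the 296 replicate 2 peaks, 273 overlapped a replicate 1 peak by at least 1 bp, or 92.2% (Clopper-Pearson 88.6 to 95.01), and 74.0% did so when the overlap had to cover 50% of both peaks. Circular shifts gave a mean of 1.66% and a maximum of 16.6% (one-sided permutation p = 0.0001, the smallest the shifts can give). In the other direction, 265 of 1174 replicate 1 peaks overlapped a replicate 2 peak, 22.6% (20.2 to 25.07), against a shifted mean of 0.426% (permutation p = 0.0001). With replicate 1 cut to its 296 strongest peaks, the overlap was 63.5% of replicate 2 peaks and 60.8% of replicate 1 peaks.

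Shared places were the strong ones. In replicate 1, the median score was 260.5 for shared and 84.8 for unshared peaks, and a shared peak outranked an unshared one with probability 0.853 (permutation p = 1e-05, for the difference of medians as well). The overlap with replicate 2 was 3.42% in the lowest 10% of replicate 1 scores, 52.1% in the second-highest bin of 10% and 88.98% in the highest. In replicate 2, the 273 shared peaks had a median score of 117 and the 23 unshared peaks 63.4. The AUC there was 0.777 (permutation p = 1e-05), while the difference of medians did not pass (permutation p = 0.0906). Across the 265 overlapping pairs, scores were correlated, with Spearman's rho of 0.762 and Pearson's r of 0.811 (permutation p = 1e-05 for each). This correlation is across peaks, which are not independent replicates.

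The whole-series list took in most of both replicate lists and added weaker peaks. It overlapped 88.9% of replicate 1 peaks and 91.9% of replicate 2 peaks. Of its own 1989 nuclear peaks, 57.4% (55.2 to 59.6) were overlapped by replicate 1, 16.3% (14.7 to 17.99) by replicate 2 and 15.3% (13.8 to 16.99) by both. The remaining 828 peaks, 41.6% (39.5 to 43.8), were overlapped by neither replicate. The median score was 17.4 for peaks found in both replicates, 8.08 for those found in replicate 1 only and 4.55 for those found in neither.

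The second question was how SMC-4 peaks were distributed over the chromosomes, and in particular between the autosomes and X, the chromosome targeted by the specialised condensin of worm dosage compensation. That condensin carries DPY-27 in place of SMC-4, so SMC-4 peaks do not measure its binding directly. X carried 480 of the 1989 whole-series peaks, or 24.1% (Clopper-Pearson 22.3 to 26.1), against 17.7% of the span. This is a 1.48-fold higher density than on the autosomes (1.33 to 1.64, two-sided exact binomial p = 4.08e-13). The test takes an even density over all chromosomes, while the autosomes themselves ran from 13.6 peaks per Mb on V to 22.9 on III, against 27.1 on X. Its p and interval, here and in each replicate list, thus do not set X against the spread between chromosomes. The excess was present in each replicate. X held 296 of 1174 peaks in replicate 1 (25.21%, 1.57-fold, 1.37 to 1.79, exact binomial p = 1.08e-10) and 79 of 296 in replicate 2 (26.7%, 1.70-fold, 1.29 to 2.204, exact binomial p = 0.000125). The replicates' X shares did not differ detectably (Fisher's exact p = 0.602, odds ratio 0.926). This test takes the 2 lists as independent, although 273 of the 296 replicate 2 peaks overlapped a replicate 1 peak. Counted in windows of 1 Mb, X windows held 27.3 ± 7.26 whole-series peaks (mean ± SD, 17 windows) and autosomal windows 18.2 ± 6.68 (80 windows, permutation p = 1e-05), a check added after the data were seen. Permuting windows does not measure the spread between chromosomes either.

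**Figure D1:**
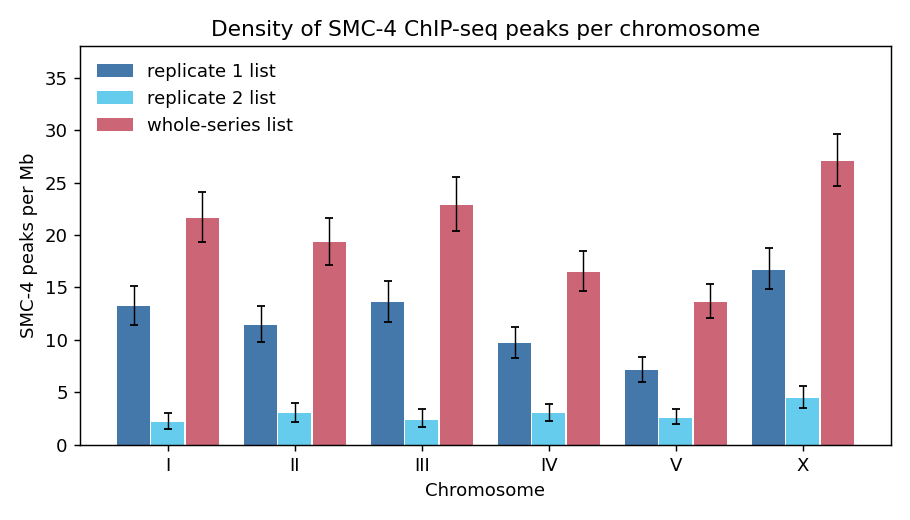
Number of SMC-4 peaks per Mb (vertical axis) on each nuclear chromosome (horizontal axis) in the 2 replicate lists and the whole-series list, with exact Poisson 95% intervals as error bars. X had the highest density in all 3 lists, with 16.7, 4.46 and 27.1 peaks per Mb.

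Among the autosomes, the densities of the whole-series list ran from 13.6 peaks per Mb on V to 22.9 on III, with 21.6 on I, 19.3 on II and 16.46 on IV. Against their shares of span, III was above (15.8% of peaks against 13.7%, adjusted exact binomial p = 0.0114), while IV (14.5% against 17.4%, adjusted p = 0.00078) and V (14.3% against 20.9%, adjusted p = 4.74e-13) were below. I and II did not pass (adjusted exact binomial p = 0.116 and 0.662), although I passed with 17.1% once peaks within 1 kb were merged (adjusted exact binomial p = 0.0196). These autosomal differences did not all pass in the single lists. Replicate 1 was low on V (12.7%, adjusted exact binomial p = 2.41e-12) and IV (14.4%, adjusted p = 0.0112), and its 15.9% on III did not pass (adjusted p = 0.051). In replicate 2 V held 18.2% (adjusted exact binomial p = 0.426), IV 17.6% (adjusted p = 0.939) and III 11.1% (adjusted p = 0.412), and X alone passed (adjusted p = 0.000753). Among whole-series peaks found in both replicates, V held 20.3%, IV 17.05% and III 11.8% (adjusted exact binomial p = 1, 1 and 0.721), while I fell below its share of span with 9.18% (adjusted p = 0.00894) and X stayed above with 26.6% (adjusted p = 0.000703). The difference between replicates in the share on V did not pass after adjustment over the 6 chromosomes (Fisher's exact p = 0.0181, adjusted p = 0.0543), and neither did that on I (16.95% against 10.8%, adjusted p = 0.0543). Because the 2 lists share most replicate 2 places and the test takes them as independent, it does not decide whether they differ.

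X also carried the strongest peaks of the whole-series list. Of the 20 highest-scoring peaks of the whole-series list, 17 lay on X, including the leading 12, against 463 of the other 1969 (23.5%, two-sided Fisher's exact p = 1.38e-08). All 20 were found in both replicates. They were 274 to 1056 bp wide and scored 57.5 to 134. The top peak, X 806296 to 806878, scored 134, with 1305 in replicate 1 and 998 in replicate 2. It was followed by X 14525399 to 14526269 (134), X 11093708 to 11094593 (128), X 6296065 to 6296847 (123) and X 13700470 to 13701077 (121). The next were X 4208557 to 4209612 (118), X 2996416 to 2997412 (104.45), X 11937067 to 11937757 (102.0), X 1344713 to 1345260 (97.1) and X 5429085 to 5429874 (92.9). Scores of 92.2 and 89.3 belonged to X 16681447 to 16682250 and X 8035979 to 8036914. The 5 other X peaks among the 20 began at 1626933, 17544252, 9465472, 16056099 and 1909368, with scores from 84.5 down to 59.1. The 17 peaks were spread from 0.806 to 17.5 Mb, with a median of 977 kb between neighbouring starts.

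**Figure D2:**
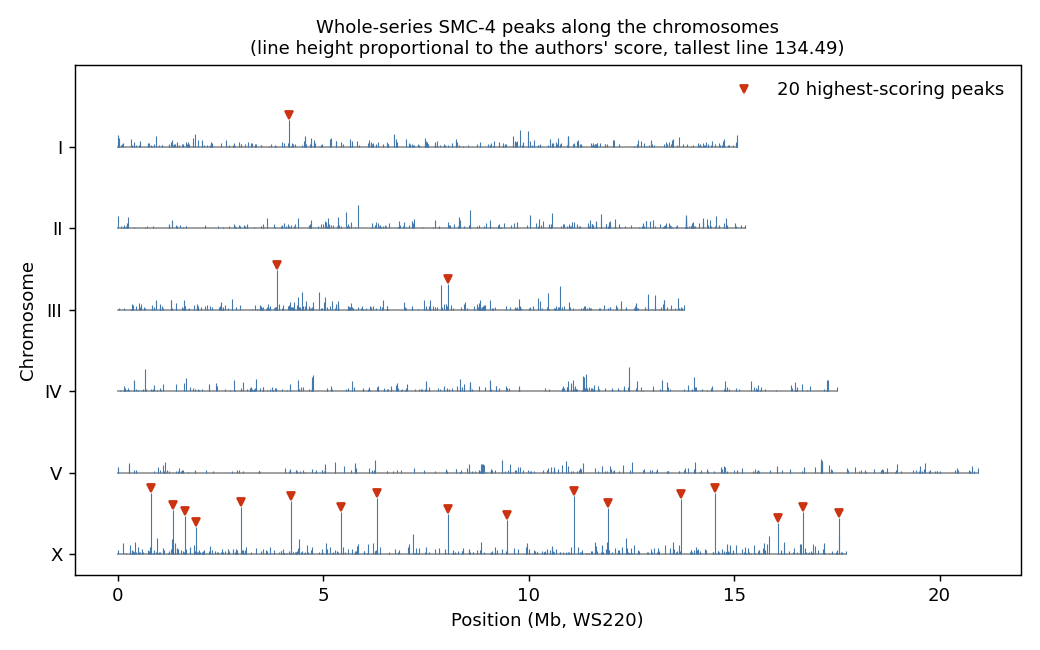
Position in Mb (horizontal axis, build WS220) of the 1989 nuclear whole-series peaks on each chromosome (rows), with line height proportional to the authors' score and triangles at the 20 highest-scoring peaks. X carries 17 of the 20 triangles, spaced along its length, and the others lie on III and I.

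The strongest autosomal peaks found in both replicates scored below the leading 12 X peaks. The leading peak of III, 3867384 to 3867684, scored 86.5 and ranked 13 of 1989. Another peak of III, 8043760 to 8044033, scored 57.5 and ranked 20. On I, the leading peak was 4171965 to 4172456 (score 58.1, rank 19). On II it was 5844563 to 5845010 (51.7, rank 24), on IV 654766 to 655036 (48.4, rank 25) and on V 17117801 to 17118853 (29.8, rank 51).

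Over all whole-series peaks, scores were higher on X than on the autosomes. The median was 7.03 on X and 6.23 on the autosomes (difference 0.8, permutation p = 0.00619), the 95th percentile was 28.18 and 22.57, and an X peak outranked an autosomal one with probability 0.549 (permutation p = 0.00117). Without the 20 highest-scoring peaks, a setting added after the data were seen, the medians were 6.95 and 6.23 (permutation p = 0.0143) and the AUC was 0.533 (permutation p = 0.0309). The X share was 16.7% (11.8 to 22.6) in the lowest 10% of scores and 32.2% (25.7 to 39.1) in the highest. Among whole-series peaks found in both replicates the AUC was 0.627 (permutation p = 0.00072). It was 0.589 in replicate 2 (permutation p = 0.0187) and 0.536 in replicate 1, where it did not pass (permutation p = 0.0651). The difference of medians passed in replicate 1 (105.5 on X against 94.9, permutation p = 0.0426). It did not pass in replicate 2 (117 against 105.6, permutation p = 0.507). The 95th percentiles on X and the autosomes were 1014 and 468 in replicate 1, and 1078 and 601 in replicate 2. Among the 20 highest-scoring peaks of each replicate, X held 10 in replicate 1 (50% against 24.8% of the others, Fisher's exact p = 0.0168) and 11 in replicate 2 (55% against 24.6%, Fisher's exact p = 0.00671). The maximum of 3100, where scores stop, was shared by 5 replicate 1 peaks, 1 of them on X, and reached by 1 replicate 2 peak, on I. Peaks on X were slightly wider in the whole-series list (median 236.5 against 223 bp, permutation p = 0.0377), which did not pass on the AUC (0.529, permutation p = 0.0516) or in either replicate (permutation p = 0.324 and 1).

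**Figure D3:**
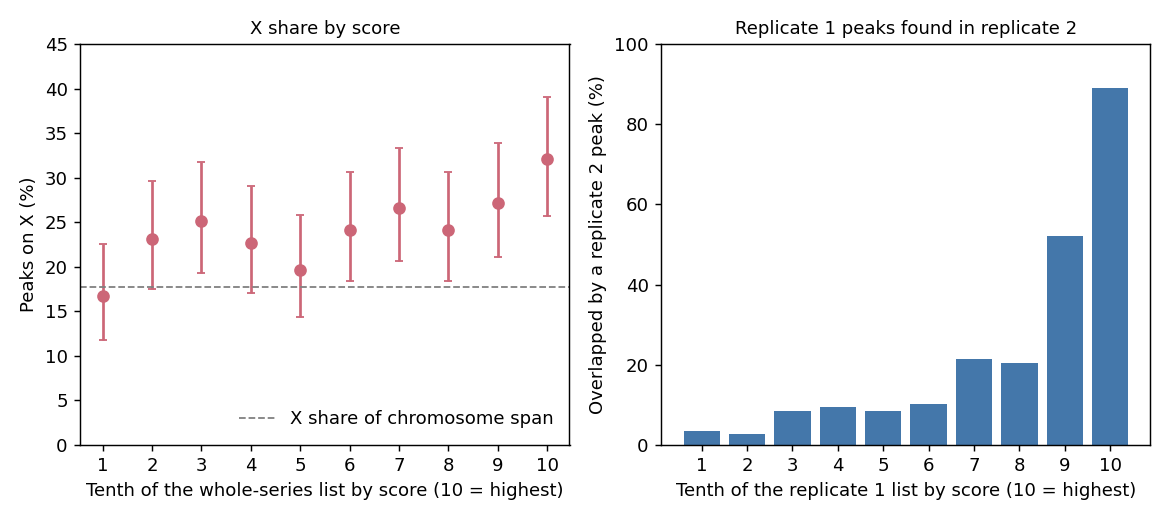
Left, percentage of whole-series peaks on X (vertical axis, with Clopper-Pearson 95% intervals) by bins of 10% of the list in order of score (horizontal axis), with the X share of span, 17.7%, dashed. Right, percentage of replicate 1 peaks overlapped by a replicate 2 peak by bins of 10% of the replicate 1 list in order of score, which was 3.42% in the lowest and 88.98% in the highest bin.

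Along the chromosomes, X peaks were fewer in the middle section, the central 33.3% of the span. It held 135 of 480 X peaks in the whole-series list, 28.1% with an interval of 24.1 to 32.4 (adjusted exact binomial p = 0.0463), and 24.0% in replicate 1 (adjusted p = 0.00161). In replicate 2 it held 25.32%, which did not pass (adjusted exact binomial p = 0.228). On the autosomes the middle section held 34.9% of whole-series peaks (adjusted exact binomial p = 0.285). The difference between X and autosomes passed in the whole-series list (odds ratio 0.729, Fisher's exact p = 0.0064), in replicate 1 (0.602, p = 0.00088) and in replicate 2 (0.547, p = 0.0398). Among X peaks found in both replicates, the middle section held 32.1% (unadjusted exact binomial p = 0.906).

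Peaks were grouped along the genome. In the whole-series list, 750 of 1989 peaks (37.7%) had a neighbour within 5 kb, against a mean of 19.8% and a maximum of 24.4% for uniform placement (permutation p = 0.0001). With peaks within 1 kb merged, the share was 23.5% against 18.1% (permutation p = 0.0001). The shares were 27.2% in replicate 1 and 25.34% in replicate 2, against 12.99% and 3.54% for placement (permutation p = 0.0001 for both). Such a neighbour was found for 37.1% of X peaks and 37.9% of autosomal peaks in the whole-series list (Fisher's exact p = 0.787). A higher peak density, as on X, raises this share by itself. Placement was not computed for X and autosomes apart, so these shares do not compare the degree of grouping. In the replicate lists the X share was lower, 22.3% against 28.8% in replicate 1 (Fisher's exact p = 0.0342) and 15.2% against 29.03% in replicate 2 (Fisher's exact p = 0.0157), unadjusted over the 3 lists.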

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

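The tests of score cutoffs, of X scores and of X windows, and the counts of whole-series peaks among the 10 highest regions, were chosen after the results were seen. Peaks on mitochondrial DNA, which entered no comparison, stood out as signal outside the main measurement: the whole-series list held 8 of them, above the limit of 3 that a count of 0 allows. They scored 9.30 to 25.43 and covered 11454 bp. Replicate 1 listed 2, covering 13355 bp up to position 13376 with scores of 290 and 1200, and replicate 2 listed 0. Whether these peaks reflect SMC-4 binding or background was not tested.

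The X chromosome carried more peaks per Mb in all 3 lists and, in the whole-series list, 17 of the 20 highest scores. A few dense clusters are argued against, since the median 1 Mb window held 28 whole-series peaks on X and 17 on autosomes (permutation p = 0.00034) and 15 of 17 X windows lay above the autosomal median. An even rise of scores along X, as from copy number or mappability, cannot be told apart from a true excess of peaks: the ratio of X to autosomal score was 1.13 at the median and 1.248 at the 95th percentile, 1.11 times as large (bootstrap interval 0.914 to 2.35), with 1.95 times in replicate 1 (1.15 to 2.898) and 1.62 times in replicate 2 (0.732 to 2.49). The interval lay above 1 in replicate 1 alone, the scale of the score is not stated, so a ratio of scores does not decide it, and input values were not analysed here. The design holds 1 antibody and 1 stage, so no biological explanation was tested.

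Wide regions were frequent among the leading peaks of the replicate lists: of the 10 highest-scoring peaks (0.852% of replicate 1 and 3.38% of replicate 2), 9 in replicate 1 and 7 in replicate 2 were at least 2 kb wide, and their best whole-series peaks ranked 74 to 164 and 74 to 140 of 1989 (the upper 3.72% to 8.25% and 3.72% to 7.04%). Peaks chosen at the top of one list are expected to lie lower in another. Over all regions of at least 2 kb the median percentile of score was 94.2 in replicate 1 and 86.7 in the whole-series list. For the regions of replicate 2 it was 86.7 and 89.7. The whole-series value is that of the best peak in each region. Percentiles in lists of 296 and 1989 peaks are also unlike, as the shorter list holds mainly strong places. Whole-series peaks overlapped by replicate 2 had a median score of 16.75, against 6.36 for the whole list. Whether wide regions stand lower in the whole-series list in general is therefore not decided. A closer tie between score and width in the replicate calls may account for part of the lead of wide regions there. Spearman's rho of width and score across peaks was 0.697 and 0.702 in the replicates and 0.511 (0.476 to 0.543) in the whole-series list. Whether the whole-series call divided these regions cannot be told apart from other causes, since the median number of its peaks was 2 over the 42 replicate 1 regions of at least 2 kb (29 held 2 or more) and 2 over the 34 of replicate 2, while 5 of the 9 and 5 of the 7 leading ones held 1 and the others 2 or more. Whether these regions are repeats was not tested, and no biological explanation was tested.

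Replicate 2 listed far fewer peaks than replicate 1. A stricter cutoff on the score is argued against, since the lowest scores differed by 0.42 (50.0 and 50.4). Detection of the stronger part of one common set of places remains a candidate explanation. Replicate 1 overlapped 92.2% of replicate 2 peaks by at least 1 bp. The 80% set beforehand was thus met under the main overlap rule, but would not be under reciprocal 50% overlap (74.0%). The AUC was 0.853 for shared against unshared replicate 1 peaks. The 92.2% rests on the full replicate 1 list. With that list cut to the length of replicate 2, the overlap was 63.5% of replicate 2 peaks and 60.8% of replicate 1 peaks. The cut list still faces all replicate 2 peaks, weak ones included, so this does not compare the strongest places alone. Of the stronger 50% of replicate 2 peaks, 95.3% overlapped the stronger 50% of replicate 1, and 23.7% did so in the other direction. Replicate 2 overlapped 88.98% of the highest 10% of replicate 1 peaks. Why replicate 2 detected less (depth, enrichment or control) stays open, as the lists hold no read counts.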

How the results depend on the processing

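Of 142 values under other settings, 89 kept direction and side of the threshold (or stayed within the interval), 21 no longer passed, 4 newly passed, 12 turned and 16 moved. For the mean of the replicate lists, the 2 values were averaged and counted as passing only where both lists passed. The mean itself was not tested. Where a replicate was left out, the list of the other replicate replaced the whole-series list, so these settings repeat the single-list values. Settings added after the data were seen were the 1 Mb windows, peaks under 1 kb, the strongest 10%, the weakest 50%, peaks in neither replicate, removal of the top 20 (for the X share and the score AUC), and the AUC for width. The X share of peaks stayed above the X share of span in all 14 settings, from 21.4% in the weakest 50% to 32.2% in the strongest 10%. Removal of the top 20 took away 17 X peaks only, too few to change this result. Replicate overlap, the AUC of shared peaks, the rank correlation and the neighbour share also passed in all settings tried. Replicate overlap fell to 74.0% of replicate 2 peaks under reciprocal 50% overlap, and to 63.5% with replicate 1 cut to the length of replicate 2. The neighbour share had a smaller excess after merging (23.5% against 18.1%). The planned comparisons with genomic features and gene lists were not run, since the gene table belongs to another assembly. No paired analysis was possible because the comparisons rest on peak lists of the ChIP samples alone. Unknown read depth limits what the shorter list could show.

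Where whole-series peaks count as found depends on the overlap rule. Under reciprocal 50% overlap, 45.45% were found in replicate 1, 10.7% in replicate 2, 9.45% in both and 53.3% in neither. With midpoints within 500 bp these were 54.1%, 14.3%, 12.5% and 44.1%. In the stronger 50% of each list 54.7% were in replicate 1 and 44.9% in neither, and after merging 14.1% were in replicate 2 and 13.1% in both.

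The number of chromosomes past the threshold was 4 as reported, 2 in the stronger 50% and 2 among peaks in both replicates. It was 3 in the replicate 1 list and 1 in the replicate 2 list, with a mean of 2. With peaks within 1 kb merged it was 5, as I newly passed (17.1%). Among peaks in both replicates, the share on I turned to 9.18% (below its 15.0% of span) and that on III to 11.8%. The mean of the replicate lists turned III to 13.5% and I to 13.9%. The replicate 1 and replicate 2 lists held 16.95% and 10.8% on I, 14.8% and 15.5% on II, 15.9% and 11.1% on III, and 14.4% and 17.6% on IV. These directions all turned in the replicate 2 list. The cause was not tested.

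The middle section of all chromosomes together held 33.28% as reported, just below its 33.33% of span. It turned to 34.6% in the stronger 50%, to 38.4% among peaks in both replicates and to 50.8% as the central 50%. In replicate 2 alone it turned to 34.8%, against 31.8% in replicate 1, and none of these passed. The autosomal middle section passed (unadjusted p) in the stronger 50% (38.3%), among peaks in both replicates (40.6%) and as the central 50% (52.8% of peaks). The X middle section did not pass in the strongest 10% (21.9%), among peaks in both replicates (32.1%) or in replicate 2 alone (25.32%). It passed in replicate 1 alone (24.0%), and the mean of the replicate lists was 24.7%. The score AUC of X against autosomes did not pass in the stronger 50% (0.537) or in replicate 1 alone (0.536). It passed in replicate 2 alone (0.589, mean of both lists 0.563), and was 0.627 among peaks in both replicates. The X width difference did not pass in the stronger 50% (19 bp), among peaks in both replicates (6 bp) or on the AUC (0.529). Neither did it pass in replicate 1 alone (15.5 bp) or replicate 2 alone (9 bp), whose mean was 12.2 bp. The cause was not tested.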

Other observations

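The left ends of chromosomes carried more peaks than their length in the replicate lists, but not detectably in the whole-series list. Within 50 kb of the left ends of the 6 nuclear spans lay 9 peaks of replicate 1 (0.767% against 0.299% of span, exact binomial p = 0.00998), 6 of replicate 2 (2.03%, exact binomial p = 0.000304) and 9 of the whole-series list (0.452%, exact binomial p = 0.211). These tests were chosen after the data were seen and are not adjusted. Right ends were left out, as spans end at the last peak, which by itself places a peak there. All 3 lists began with a peak at the first base of chromosome I, which ended at 454 in the whole-series list (score 25.99), at 677 in replicate 1 (score 999.7) and at 498 in replicate 2 (score 666).

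How many X peaks stood at the top of the replicate lists depended on the peak widths counted. Among all peaks, X held 10 and 11 of the top 20 of replicates 1 and 2. Among peaks narrower than 1 kb it held 15 and 16, close to the 16 of the whole-series list with the same limit. These counts by themselves do not show that the same X peaks were on top in each list. By position, the 17 X peaks among the 20 highest of the whole-series list ranked 10 to 54 among all replicate 1 peaks. In replicate 2 they ranked 7 to 121. The leading 12 of them ranked 10 to 37 and 7 to 32. The strong and spaced X peaks of the whole-series list may correspond to recruitment sites of the dosage compensation complex, whose condensin shares subunits with the SMC-4 complexes but carries DPY-27 in place of SMC-4. This hypothesis was not tested, as no positions of such sites were used here. The excess on X was also present among the weakest 50% of whole-series scores, with 21.4% against 17.7% of the span. Recognition of a related protein by the antibody, or open chromatin that enriches in many immunoprecipitates, could give the same picture and were not tested either.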
